A study of Homo sapiens with 6 samples.

How the data were processed

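Total RNA of 2 human cell lines was compared on Illumina expression arrays, with 3 arrays of C28, a chondrocyte line that the labels name as the control, and 3 arrays of JJ012, a chondrosarcoma line. Per the labels, 5000000 cells were seeded in dishes and incubated for 24 h before lysis and column purification of RNA, and labelled cRNA was made with a kit for Illumina arrays. The series title names the NOTCH and IGF receptor pathways, and a companion measurement of microRNA was not used here. The labels do not say that arrays of a line came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Precision is limited by the number of arrays.

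Each array gave a mean intensity for 47231 probes, which the authors deposited on a linear scale without background subtraction or scaling between arrays. The deposited table also gives a fraction per probe and array under a detection p-value heading. Bright probes are at 1 in that column, so it was read as 1 minus the detection p. Scanner software is not given in the sources used here. A further table holds the authors' normalized log2 values of the same arrays. Each probe is centred there on its median over the 6 arrays, with array medians of −0.001, −0.001 and 0 for C28 and −0.003, 0.004 and 0.003 for JJ012. Its log2 scale, centring and direction were found by setting differences between its columns against those of the intensities, while the authors' method of normalizing between arrays stays unknown. That table served as an alternative only.

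Intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and negative controls inferred from the detection values. A probe was kept when its detection p was under 0.01 on all 3 arrays of at least 1 line, which left 19384 probes. Gene names came from the platform annotation and were checked through Entrez identifiers against a RefSeq gene table of assembly GRCh38.p14, which was used only for names and for the order of neighbouring genes. Of all probes, 30113 had 1 symbol, 8 had several and 17110 had no gene listed, and 30074 matched the RefSeq table. Probes with several symbols or no listed gene stayed out of gene counts. For a gene with more than 1 probe past the filter, the probe with the highest mean signal was used. Of 11515 genes tested, 3132 had more than 1 such probe, and in 51 another probe was called in the opposite direction.

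JJ012 was compared with C28 by limma (lmFit and eBayes, two-sided), and every adjusted p for a gene comes from this fit with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05 and a fold change of at least 2. Fold changes are log2 of JJ012 minus C28. Where a gene, or the probe used for it, was not detected on any array of a line, or on any kept when an array was left out, the size of its change was given only as a bound. The mean of the brighter line was set against the mean, per array, of the higher of the lowest signal among detected probes and the probe's own signal, and the bound is written as at least N-fold. It is the bound of the probe used, and dimmer probes of the same gene give smaller ones.

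Before the data were examined, the fit, the filter, the 36 gene lists, the rule for named genes and the main alternatives were fixed. Named genes were the 8 largest changes in each direction among genes whose probe was detected on all 6 arrays, and the 5 brightest genes in each direction among those detected in 1 line only. They also included a fixed set of NOTCH and IGF genes, and the called members with the largest changes of each other list. Other genes named below were chosen after their values were seen. Lists were tested with camera of limma (preset correlation between genes of 0.01), which compares a list with the other genes. The adjusted p was taken over all lists, and every list p below is from camera unless another test is named. Of the 6 lists past an adjusted p of 0.05, none held that call with a correlation estimated from the data. Limma's fry was run as well. Its directional p asks whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction, and neither compares a list with other genes. For every list, the numbers called higher and lower adjusted over the list alone equalled those adjusted over all genes.

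The lists covered the NOTCH pathway, the IGF axis, cartilage matrix, hypertrophy, matrix proteases, fibrillar matrix, hedgehog, WNT, TGF-beta and BMP signalling, receptor tyrosine kinases, cell cycle genes, cell cycle inhibitors, p53 targets, interferon-stimulated genes and antigen presentation. They also covered cytokines, miRNA machinery, imprinted genes, cancer-testis antigens, HOX genes, mesenchymal transcription factors, integrins, glycolysis, the citrate cycle, the respiratory chain, cholesterol synthesis, serine metabolism, ribosomal proteins, heat shock genes and histones. Markers of epithelial, endothelial, blood, muscle, neural and adipose cells completed them.

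The steps were tested on simulated arrays of the same 2 groups with 13238 genes in the step. Of 93 genes planted at a log2 change of 1.5 that passed the filter, 90 were called, and all 93 planted at 3 were called. Of 13052 unchanged genes, 1 was called, and of 100 random lists none was called. Both groups were built from C28 means, with few planted changes, as often up as down. Noise was independent between genes and smaller than in JJ012 for the leading lower genes. In the data 31.2% of genes were called, so normalization under so many changes and lists of correlated genes were not tested by the simulation. In a separate step of 47231 probes, a C28 share of 10% planted in JJ012 replicate 1 was read back as 10.1% over 56 probes.

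To measure signal of one line on arrays of the other, probes were taken whose C28 mean lay over 1000 above background and that were off on JJ012 replicate 2, and their signal was expressed as a percent of the C28 mean. The files give no slide, so no fit used it. Alternatives comprised other background corrections, normalizations, filters, probe rules, thresholds and variance models, array weights, the replicate number as a block, and each array left out in turn. After the data were seen, subtraction of the measured C28 share from JJ012 replicates 1 and 3 and a fit with JJ012 replicate 2 as the lone JJ012 array, which takes the spread from the C28 arrays, were added. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes on the Y chromosome and XIST are not reported.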

Results

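Gene expression was measured in C28 chondrocytes and JJ012 chondrosarcoma cells, with 3 arrays of each line. The comparison asks how the sarcoma line differs from the chondrocyte line, with the NOTCH pathway and the IGF axis as the topics named by the series title. On the C28 arrays 18922, 19332 and 19301 of 47231 probes were detected, and on the JJ012 arrays 17888, 17826 and 18378. Median intensities were 101.6, 90.8 and 95.8 for C28 and 84.8, 84.4 and 95.6 for JJ012. Over 15285 probes detected on all 6 arrays, the correlation across probes of normalized log2 signal was 0.994 to 0.996 within C28, 0.986 to 0.992 within JJ012 and 0.891 to 0.907 between the lines. Probes are not independent replicates.

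The germline antigen genes of the GAGE family were the genes most increased in JJ012 among those whose probe was detected on all 6 arrays. GAGE2A read 6.64 ± 0.71 in C28 and 14.03 ± 0.03 in JJ012 (log2, SD, n = 3 each), a log2 fold change of 7.39 (SE 0.31, adjusted p = 8.55e-07). The 7 other leading genes were GAGE12B, GAGE12J, GAGE12F, GAGE12C, GAGE12G, GAGE12H and GAGE4, down to a log2 fold change of 6.36 for GAGE4 (SE 0.32, adjusted p = 1.87e-06). These genes are near-identical copies that probes may not separate, so they count as 1 uncertain family signal. The C28 arrays carried a median of 0.543%, 0.795% and 0.307% of the JJ012 level of genes measured in JJ012 and off on the other C28 arrays. The GAGE genes named here had the same order of C28 arrays, with GAGE2A at 6.88, 7.21 and 5.85 on replicates 1, 2 and 3. Whether their C28 signal is expression in C28 or signal of JJ012 was not tested. In the latter case their fold changes are too small. Among genes detected on all JJ012 arrays and no C28 array, GTSF1, a germline gene of transposon silencing, was at least 77.7-fold higher (adjusted p = 3.62e-08). SPANXA2 was at least 62.8-fold, SPANXC at least 60.8-fold, CT55 at least 58.4-fold and TM4SF19 at least 54.8-fold higher. The SPANX copies are also near-identical.

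ACTG2, which encodes a smooth muscle actin, led the lower genes whose probe was detected on all 6 arrays. ACTG2 fell from 13.18 ± 0.15 in C28 to 8.09 ± 1.96 in JJ012, a log2 fold change of −5.09 (SE 0.82, adjusted p = 0.000721). IGFBP5, an IGF-binding protein, followed at −5.01 (SE 0.69, adjusted p = 0.000299), and without JJ012 replicate 2 it was ahead, at −4.22 against −4.12 for ACTG2. EEF1A2, a translation elongation factor, fell by 4.81 on the log2 scale, CRIP1 by a log2 change of −4.73, the vasodilator peptide gene ADM by −4.56, the growth factor gene MDK by −4.42, BTBD6 by −4.37 and ACAA2, an enzyme of fatty acid oxidation, by −4.34. Among genes detected on all C28 arrays and no JJ012 array, RAB36 was at least 13.5-fold lower (adjusted p = 6.35e-06), INPP1 at least 11.6-fold, NACAD at least 10.6-fold, the tight junction gene CLDN1 at least 10.2-fold and PPP2R2C at least 10.1-fold lower. The other 3 probes of MDK read −1.60, −1.69 and −1.64. The other probes of NACAD, also undetected in JJ012, gave bounds of only at least 1.45-fold and 2.26-fold, and that of PPP2R2C at least 4.72-fold. Genes that JJ012 replicate 1 detected could not enter the ranking of genes detected in C28 only, and that array carried C28 signal, as given below. Without that array FZD6 was at least 35.0-fold and IGFBP4 at least 26.2-fold lower. For the 8 genes detected on all arrays, the log2 fold changes ran from −6.08 to −4.89 without JJ012 replicate 1 and from −4.22 to −3.78 without JJ012 replicate 2.

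In total 3594 of 11515 genes (31.2%) were called, 1572 higher and 2022 lower in JJ012, by limma at an adjusted p under 0.05 and at least 2-fold. Lower genes made up 56.3% of the calls, and 67.0% when arrays were scaled to a common median, a scaling that moved the median log2 fold change of all genes from −0.04 to −0.23. Of the called genes, 203 were higher and 320 lower by a fitted change of at least 8-fold, in which genes not detected in 1 line enter at their fitted value. Detection in 1 line alone covered 415 of the higher and 614 of the lower genes. Of 1119 probes detected on all C28 arrays and off on JJ012 replicates 2 and 3, JJ012 replicate 1 detected 123, so the 614 may be too few. For 76.2% of all tested genes the 3 values of a line did not overlap those of the other line, against 10% by chance. The median within-line SD was 0.11 in C28 and 0.15 in JJ012.

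Probes bright in C28 and off on JJ012 replicate 2 carried signal on JJ012 replicate 1. Over 57 such probes, JJ012 replicate 1 read a median of 10.7% of the C28 mean (10th to 90th percentile 9.48% to 12.4%), with all 57 detected. JJ012 replicate 3 read 2.57% (10th to 90th percentile 1.70% to 3.55%) with 39 detected, and JJ012 replicate 2, which was off by selection, read 0.509%. ACTG2 read 11.7%, 0.633% and 2.86% of the C28 mean on JJ012 replicates 1, 2 and 3, and IGFBP5 9.99%, 0.840% and 2.75%. The probes used for FZD6, IGFBP4, SGCE, CDKN2A, HERC5, UCHL1 and CXCL1, named below, are among the 57. Their percents on JJ012 replicate 1 are thus part of that median and no separate evidence for it. JJ012 replicate 1 was the highest JJ012 array in 67.5% of all genes called lower, in 98.4% of the 320 with a fitted fall of at least 8-fold, and in 27.6% of genes called higher. Without JJ012 replicate 1, 1612 genes were higher and 2079 lower. With JJ012 replicate 2 as the lone JJ012 array, an alternative added after the data were seen, 1632 genes were higher and 2089 lower, of which 1430 and 1894 were also called with all arrays. That fit has no spread between JJ012 arrays and assumes that the lone array varies like the C28 arrays, so its numbers are not a like-for-like test.

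**Figure D1:**
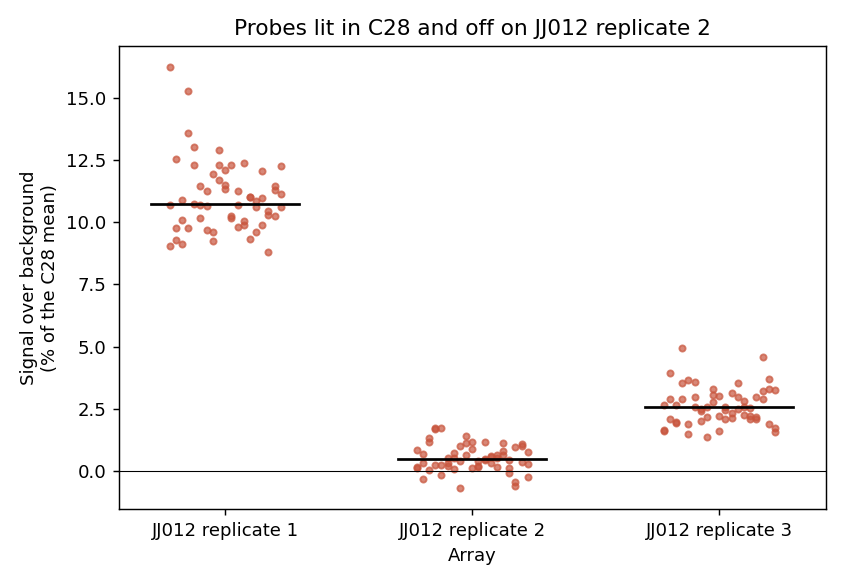
Signal over background of 57 probes bright in C28 and off on JJ012 replicate 2, as a percent of the C28 mean (vertical axis) on each JJ012 array (horizontal axis), with points for probes and bars for medians. The medians were 10.7%, 0.509% and 2.57% for replicates 1, 2 and 3, and replicate 2 is low by selection.

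Genes of NOTCH signalling, which links ligands on one cell to receptors on its neighbour, differed in both directions. The ligand gene JAG2 was at least 4.51-fold lower in JJ012 (adjusted p = 3.53e-06), the receptor gene NOTCH3 at least 3.72-fold, the ligand gene DLL1 at least 2.77-fold and the target gene HEYL at least 2.21-fold lower. None of these was detected on a JJ012 array. JAG1 fell from 8.45 ± 0.10 to 6.79 ± 0.35 (log2 fold change −1.66, SE 0.17, adjusted p = 6.48e-05). HES1, a NOTCH target, read 9.21 ± 0.08 in C28 and 6.62 ± 1.07 in JJ012, where 2 of 3 arrays detected it (log2 fold change −2.59, SE 0.45, adjusted p = 0.00115), and JJ012 replicate 1 read 30.5% of its C28 mean. The target gene HEY2 rose from 7.12 ± 0.07 to 8.68 ± 0.09 (log2 fold change 1.56, SE 0.09, adjusted p = 4.19e-06) and RBPJ, the DNA-binding partner of activated NOTCH, from 7.60 ± 0.04 to 8.98 ± 0.06 (1.38, SE 0.09, adjusted p = 5.17e-06). NOTCH1 at −0.74, NOTCH2 at 0.74 and HEY1 at 0.59 had adjusted p-values of 0.000451, 0.000184 and 0.000897 without a 2-fold change. NOTCH4 was not detected on any JJ012 array, which bounds its difference at 1.47-fold or more, and it was not called (adjusted p = 0.000282). Its fitted difference passed 2-fold without JJ012 replicate 2, with median scaling, with array weights and with subtraction of the C28 share from JJ012 replicates 1 and 3, but its signal in JJ012 is at background. DLL4 and NRARP did not pass the detection filter.

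Of 34 measured NOTCH genes 4 were higher, 8 lower and 22 not called. HES7 and DTX2 completed the higher genes, and APH1B and MAML1 the lower ones, named after their values were seen. Of all tested genes 31.2% were called. The list as a whole did not stand apart from other genes (camera adjusted p = 0.77), whereas fry gave an adjusted p of 0.0159 for a shift down and 6.5e-06 for change in either direction. The latter does not set NOTCH genes apart, since the respiratory chain list, with 0 genes called, had the same value. In every list the fry adjusted p for change in either direction was at most 0.00652. Over genes detected on all 6 arrays the camera direction was up (adjusted p = 0.614). Without background correction DLL1 no longer passed 2-fold.

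Among genes for IGF-binding proteins, which bind IGFs outside the cell, IGFBP2 to IGFBP7 were lower in JJ012 and IGFBP1 was at least 2.74-fold higher. IGFBP5 fell from 12.63 ± 0.19 to 7.62 ± 1.63 and IGFBP4 from 10.38 ± 0.12 to 5.52 ± 1.42 (log2 fold change −4.87, SE 0.60, adjusted p = 0.000161), with IGFBP4 detected on 1 of 3 JJ012 arrays. IGFBP2 at −1.64, detected on 1 JJ012 array, IGFBP6 at −1.08, IGFBP7 at −1.07 and IGFBP3 at −1.06 were lower by less. IGF1R, the IGF receptor gene, was at least 2.60-fold lower (adjusted p = 1.54e-05), IGF2BP1 at least 1.99-fold and IGF2 at least 1.11-fold, none of them detected on a JJ012 array. IRS2, an adaptor of the receptor, rose from 8.84 ± 0.03 to 10.34 ± 0.37 (log2 fold change 1.5, SE 0.18, adjusted p = 0.000124). IRS1 read −0.03 (adjusted p = 0.868), IGF2R 0.61, IGF2BP2 −0.68 and IGF2BP3 −0.43 (adjusted p = 0.139), all without a call. IGF1 and INSR did not pass the detection filter.

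IGFBP4 read 9.61% of its C28 mean on JJ012 replicate 1 and 1.36% on replicate 3. Without JJ012 replicate 1 no JJ012 array detected IGFBP4, which was then at least 26.2-fold lower, and the log2 fold change of IGFBP5 was −5.85. Without JJ012 replicate 2 the log2 fold changes were −4.33 for IGFBP4 and −4.22 for IGFBP5. IGFBP3 lost its call without C28 replicate 3 (−0.98), without JJ012 replicate 3 (−0.85) and with the mean of its probes (−0.98). Of 31 measured IGF genes 4 were higher, 12 lower and 15 not called. Besides those above, STC1 at 3.66 and PIK3R1 at 1.57 were higher, and STC2 at −1.62, GRB10 at −2.22 (detected on 1 of 3 JJ012 arrays) and PAPPA, at least 2.17-fold, were lower. STC1, STC2, PIK3R1, GRB10, PAPPA and IGFBP1 were named after their values were seen. The camera adjusted p was 0.206, while fry gave 0.00181 for a shift down and 3.53e-06 for change in either direction. The glycolysis and hypoxia list had the same fry value for change in either direction, so it does not set IGF genes apart. Without background correction IGFBP2 at −0.88 and IGFBP3 at −0.87 did not pass 2-fold, nor did IGF1R, IGF2 and IGF2BP1, which no JJ012 array detected. With the authors' normalized values IGFBP2 at −0.96, IGFBP3 at −0.90, IGF2 and IGF2BP1 did not, and with normexp without negative controls IGFBP3 at −0.91, IGF2 and IGF2BP1 did not. Another probe of IGFBP3 read −0.89. With JJ012 replicate 2 as the lone JJ012 array, where the spread comes from the C28 arrays alone, IGFBP3 at −0.59 and IGFBP6 at −0.97 lost the call, and IGF2BP3 gained it at −1.03.

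**Figure D2:**
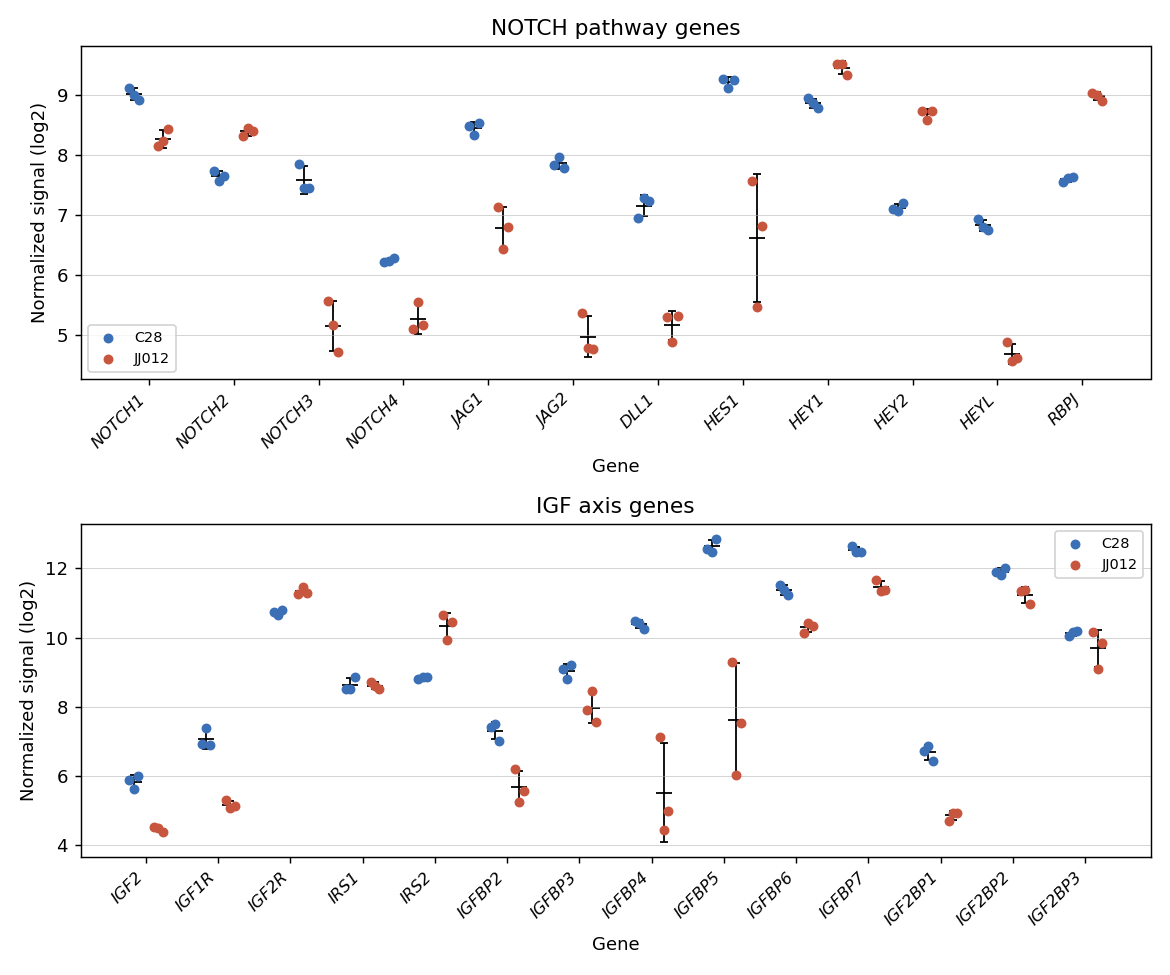
Normalized log2 signal (vertical axis) of NOTCH and IGF genes (horizontal axis) on each array, with blue points for C28, red points for JJ012 and black bars for the mean and SD of 3 arrays. JAG2 read 7.86 ± 0.09 in C28 against no detection in JJ012, and HEY2 and RBPJ were higher in JJ012.

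Genes of the cancer-testis antigen list, many but not all of them normally restricted to germ cells, were higher in JJ012 in 20 of 22 measured cases and lower in 2 (camera adjusted p = 3.26e-09, and adjusted p = 0.484 with an estimated correlation). MAGEC2 rose by a log2 fold change of 7.10 (SE 0.26, detected on 2 of 3 C28 arrays) and MAGEA1 by 6.97 (SE 0.14, 1 of 3). MAGEC2 read 5.88, 5.99 and 4.92 on C28 replicates 1, 2 and 3, and whether this is expression in C28 was not tested. MAGED1, bright in both lines at 12.33 in C28 and 11.04 in JJ012, was lower at −1.29. MAGED4, undetected in JJ012, was lower without a bound on its fold. The median log2 fold change of the list was 5.23, and 4.54 with undetected genes at their bounds. Probes of the MAGEA and GAGE copies may read one another.

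HOX genes, the homeobox genes of body position, were lower in 11 of 19 measured cases and higher in 1 (camera adjusted p = 0.0208, and adjusted p = 0.484 with an estimated correlation). HOXC4 fell by 3.41 on the log2 scale (log2 fold change −3.41, SE 0.36, adjusted p = 6.86e-05) and HOXB8 was at least 6.17-fold lower, while HOXD4 was at least 1.95-fold higher. Imprinted genes, expressed from 1 parental copy, were lower in 13 of 22 cases and higher in 2 (camera adjusted p = 0.0279, and adjusted p = 0.524 with an estimated correlation). SGCE had a log2 fold change of −4.52 (SE 0.57, detected on 2 of 3 JJ012 arrays) and TFPI2 of −4.19 (SE 0.47, 1 of 3), while MKRN3 was at least 3.97-fold and H19 at least 1.61-fold higher. On JJ012 replicate 1 SGCE read 11.5%, TFPI2 11.8% and HOXC4 17.4% of the C28 mean. Without JJ012 replicate 1 SGCE was at −5.25 and TFPI2, then detected on no JJ012 array, was at least 15.1-fold lower, and without JJ012 replicate 2 SGCE was at −3.92. The Imprinted genes list lost its call over genes detected on all 6 arrays (adjusted p = 0.456).

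Neural markers were lower in 6 of 8 measured cases and higher in none by limma, the same numbers at an unadjusted p under 0.05 and 2-fold (camera adjusted p = 0.0208, and adjusted p = 0.539 with an estimated correlation). UCHL1, a ubiquitin hydrolase of neurons, had a log2 fold change of −4.89 (SE 0.66, detected on 2 of 3 JJ012 arrays), with −5.76 without JJ012 replicate 1 and −4.22 without JJ012 replicate 2, and it read 10.8% of its C28 mean on JJ012 replicate 1. The Neural markers list lost its call with no filter (adjusted p = 0.115) and with a looser one (0.138). Hedgehog signalling genes were lower in 6 of 9 cases and higher in none by limma, again the same at an unadjusted p under 0.05 and 2-fold (camera adjusted p = 0.048, and adjusted p = 0.539 with an estimated correlation). GAS1, a co-receptor, fell by 3.31 on the log2 scale (log2 fold change −3.31, SE 0.28, detected on 2 of 3 JJ012 arrays) and read 13.2% of its C28 mean on JJ012 replicate 1. The Hedgehog signalling list lost its call over genes detected on all 6 arrays (adjusted p = 0.437), with median scaling (0.0594), with cyclic loess (0.0574) and without C28 replicate 1 (0.0609).

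Antigen presentation genes were lower in 9 of 19 measured cases and higher in 2 (camera adjusted p = 0.048, and adjusted p = 0.539 with an estimated correlation). The class I genes HLA-B and HLA-C had log2 fold changes of −4.11 (SE 0.48) and −3.02 (SE 0.22), with HLA-C detected on 2 of 3 JJ012 arrays, whereas HLA-DMA rose by 1.43 and HLA-E by 1.04. On JJ012 replicate 1 HLA-B read 12.8% and HLA-C 16.2% of the C28 mean, and HLA-B was at −4.70 without that array and at −3.58 without JJ012 replicate 2. Probes of HLA genes may read one another, and HLA-E lost its call without JJ012 replicate 1 (0.98), with median scaling (0.84) and with JJ012 replicate 2 as the lone JJ012 array (0.89). The Antigen presentation list lost its call without C28 replicate 1 (adjusted p = 0.0609), C28 replicate 2 (0.0516), JJ012 replicate 2 (0.0536) or JJ012 replicate 3 (0.0588), with median scaling (0.0755), cyclic loess (0.0653) or the mean of a gene's probes (0.103), and over genes detected on all 6 arrays (0.0518).

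**Figure D3:**
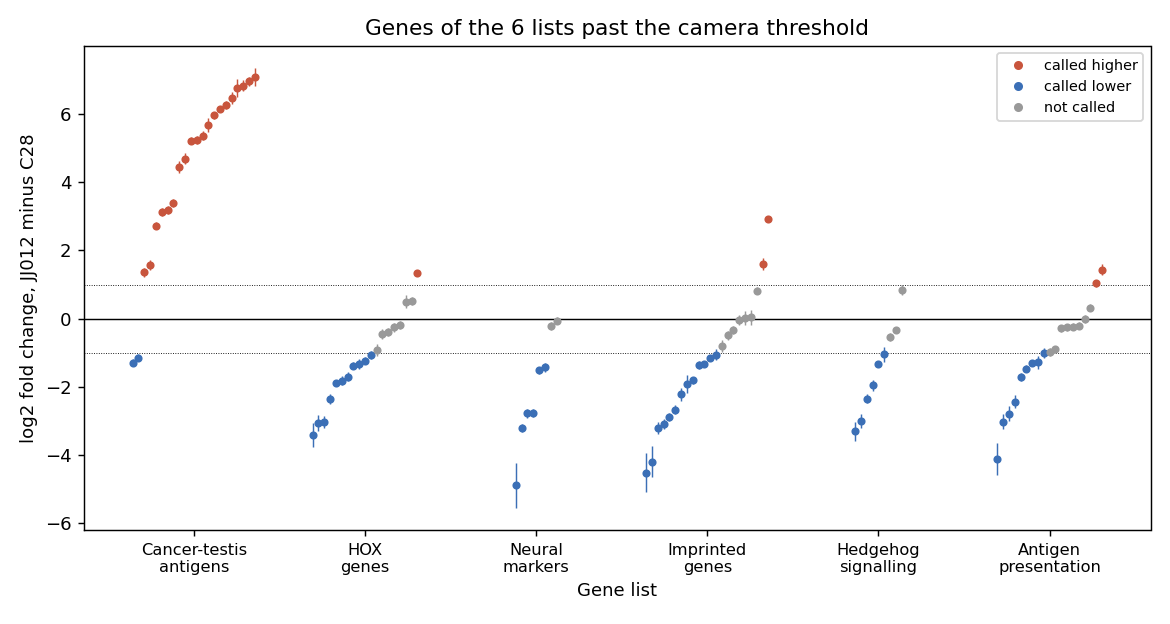
Log2 fold change of JJ012 minus C28 (vertical axis, bars show the SE) for each measured gene of the 6 lists with a camera adjusted p under 0.05 (horizontal axis), with red for genes called higher, blue for lower and grey for not called. Genes of the cancer-testis antigen list lie above 0 in 20 of 22 cases, dotted lines mark a 2-fold change, and genes undetected in 1 line are drawn at fitted values that are not bounds.

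Of 30 cartilage matrix and chondrocyte genes only 5 passed the filter, and 3 of them were lower with none higher by limma, the same numbers at an unadjusted p under 0.05 and 2-fold (camera adjusted p = 0.171). CYTL1, a cytokine-like gene of chondrocytes, fell by 3.91 on the log2 scale (log2 fold change −3.91, SE 0.45, detected on 1 of 3 JJ012 arrays), and read 13.7% of its C28 mean on JJ012 replicate 1, without which no JJ012 array detected it and it was at least 12.2-fold lower. MATN3 and NKX3-2 were the other lower genes, chosen after their values were seen. Of 10 hypertrophy and osteogenic genes 1 was higher and 4 lower (adjusted p = 0.236). SPP1, which encodes osteopontin, was at least 8.40-fold higher, and TNFRSF11B, which encodes osteoprotegerin, fell by 3.23 (SE 0.24, 1 of 3 JJ012 arrays), beside RUNX2, RUNX3 and ANKH, named after their values were seen. Of 19 matrix proteases and inhibitors 6 were higher and 6 lower (adjusted p = 0.37). TIMP4 was at least 35.0-fold and the stromelysin gene MMP3 at least 21.6-fold higher, while PLAU, which encodes urokinase, fell by 4.34 (SE 0.49) and MMP11 by 3.55 (SE 0.34, 1 of 3 JJ012 arrays). PLAU was at −3.74 without JJ012 replicate 2 and read 10.4% of its C28 mean on JJ012 replicate 1.

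Fibrillar and fibroblast matrix genes were lower in 17 of 30 cases and higher in 7 (adjusted p = 0.063). The proteoglycan gene DCN was at least 35.1-fold higher by its brightest probe, and its other probes, also undetected in C28, gave bounds of only at least 1.57-fold and 7.19-fold. The collagen cross-linking enzyme gene LOX rose by a log2 fold change of 5.32 (SE 0.15), while the collagen gene COL5A2 fell by 4.14 (SE 0.46) and FBN2 by 3.80 (SE 0.40, detected on 2 of 3 JJ012 arrays). COL5A2 read 13.3% of its C28 mean on JJ012 replicate 1 and was at −4.74 without that array. WNT signalling genes were lower in 15 of 28 cases and higher in 2 (adjusted p = 0.063). WNT5B rose by 3.27 (SE 0.12) and FZD1 by 1.18 (SE 0.13), which lost its call with median scaling (0.96), with array weights (0.99) and by another probe (0.93). The secreted WNT inhibitor gene DKK1 fell by 5.00 (SE 0.91, adjusted p = 0.00145, 2 of 3 JJ012 arrays) and the receptor gene FZD6 by 4.74 (SE 0.80, 1 of 3). Without JJ012 replicate 1 DKK1 was at −6.07 and FZD6, then detected on no JJ012 array, was at least 35.0-fold lower, and without JJ012 replicate 2 they were at −3.89 and −4.02. The Fibrillar and fibroblast matrix list and the WNT signalling list passed 0.05 without JJ012 replicate 1 (adjusted p = 0.024 each) and under other settings.

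In the TGF-beta and BMP list 6 of 29 genes were higher and 13 lower (adjusted p = 0.307). FST, an activin antagonist, rose by 2.95 and TGFBR3 by 2.31, while BMP7 fell by 4.33 (SE 0.46) and GREM1 by 3.77 (SE 0.37), each detected on 1 of 3 JJ012 arrays. BMP7 read 9.97% of its C28 mean on JJ012 replicate 1, without which no JJ012 array detected it and it was at least 14.8-fold lower. Of 30 receptor tyrosine kinase and ligand genes 8 were higher and 6 lower (adjusted p = 0.543), with FGF5 at least 10.2-fold higher, FGF18 at least 8.39-fold higher by its brightest probe, and TGFA at least 3.45-fold and PDGFB at least 3.59-fold lower. No C28 array detected that probe of FGF18, and its other probe, detected on all C28 arrays, read 0.03 and was not called. Of 23 integrins and matrix receptors 5 were higher and 7 lower (adjusted p = 0.683), led by ITGA10 at least 13.1-fold and ITGA2 at 2.61 higher, and GPC4 at least 7.70-fold and ITGB3 at least 2.58-fold lower. ITGA5, ITGA6 and GPC6 completed the higher genes, named after their values were seen. Among 16 mesenchymal transcription factors and cadherins 4 were higher and 6 lower (adjusted p = 0.683). PRRX1 was at least 17.0-fold higher and SNAI2 rose by 3.88, MSX2 fell by 2.66 (1 of 3 JJ012 arrays) and CDH11 by 2.30, and TWIST1 and TBX15 were also higher, named after their values were seen. This list had a median of −0.47 and a mean of 0.17, with camera pointing down and fry up (fry adjusted p = 0.0218).

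Cell cycle genes were lower in 12 of 48 cases and higher in 2 (adjusted p = 0.063). UBE2C, a ubiquitin-conjugating enzyme of mitosis, fell by 1.86 (SE 0.12) and the mitotic kinase gene AURKA by 1.57 (SE 0.11), while BIRC5 rose by 1.41 (SE 0.21) with another probe at 0.73 and not called, and CDC6 by 1.36 (SE 0.16). Without JJ012 replicate 2 the Cell cycle and proliferation list passed 0.05 (adjusted p = 0.0285). Among 19 cell cycle inhibitors and cyclin D genes 7 were lower and 2 higher (adjusted p = 0.0733). CCND1, which encodes cyclin D1, rose by 1.71 (SE 0.11) and CDK6, named after its value was seen, was the other higher gene. CDKN2A, which encodes p16 and ARF, fell by 4.32 (SE 0.46, detected on 2 of 3 JJ012 arrays). It read 9.77%, 0.672% and 3.95% of its C28 mean on JJ012 replicates 1, 2 and 3. Its log2 fold change was −4.87 without JJ012 replicate 1 and −3.78 without JJ012 replicate 2. Of 20 p53 target genes none was higher and 4 were lower by limma, the same numbers at an unadjusted p under 0.05 and 2-fold (camera adjusted p = 0.535). RRM2B fell by 1.60 (SE 0.09), beside DDB2, TP53INP1 and TNFRSF10B, named after their values were seen.

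Interferon-stimulated genes were lower in 14 of 38 cases and higher in 6 (adjusted p = 0.0733). IFI44L was at least 10.7-fold higher by its brightest probe, which no C28 array detected, while another probe, detected on 2 of 3 C28 arrays, read 0.71 and was not called. IFI44 rose by 2.54 (SE 0.17), while EPSTI1 fell by 4.16 (SE 0.35, 1 of 3 JJ012 arrays) and HERC5 by 4.04 (SE 0.51, 2 of 3). HERC5 was at −4.65 without JJ012 replicate 1, where it read 13.6% of its C28 mean, and at −3.45 without JJ012 replicate 2. Of 31 cytokine and chemokine genes 15 were lower and 6 higher (adjusted p = 0.0986). TNF was at least 2.60-fold and CCL20 at least 2.87-fold higher, while the chemokine genes CXCL1 and CCL2 fell by 4.34 (SE 0.56, 2 of 3 JJ012 arrays) and 4.04 (SE 0.32, 1 of 3). CXCL1 was at −5.04 without JJ012 replicate 1, where it read 11.7% of its C28 mean. EPSTI1 and CCL2 read 8.91% and 8.80% of their C28 means on that array. Without it no JJ012 array detected them, and they were at least 11.5-fold and 10.3-fold lower.

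Glycolysis and hypoxia genes were higher in 6 of 32 cases and lower in 2 (adjusted p = 0.535), with CA12, a carbonic anhydrase, at least 18.8-fold higher and ADM and P4HA2 lower, P4HA2 being named after its value was seen. In the citrate cycle and glutamine list 2 of 28 were higher and 7 lower (adjusted p = 0.063). PC, which encodes pyruvate carboxylase, rose by 2.07 (SE 0.20) and the isocitrate dehydrogenase gene IDH2 fell by 2.15 (SE 0.10), with SDHD also higher and named after its value was seen. Of 41 respiratory chain genes limma called 0, with 28 at an adjusted p under 0.05 at any fold, 30 at an unadjusted p under 0.05 and 0 when 2-fold was also asked (camera adjusted p = 0.561). Cholesterol synthesis had 1 of 18 genes higher and 2 lower (adjusted p = 0.34), with DHCR7 up by 1.22, EBP down at −3.80 (2 of 3 JJ012 arrays) and HMGCS1 lower, named after its value was seen. DHCR7 lost its call with median scaling (0.99). Serine and one-carbon metabolism had 3 of 17 higher and 1 lower (adjusted p = 0.856). CTH, which makes cysteine, was at least 8.41-fold higher, SLC7A11 and ASNS were also higher, named after their values were seen, and SHMT2 at −1.03 lost its call without JJ012 replicate 3 (−0.996) and with JJ012 replicate 2 as the lone JJ012 array (−0.97).

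Whether each member of the miRNA machinery list makes or loads microRNA was not checked. That list had 1 of 23 genes higher, GEMIN4 at 1.04, and 1 lower, ZCCHC3 at −1.68 (camera adjusted p = 0.991). Its median was −0.003 and its mean −0.06, with camera pointing up and fry down (fry adjusted p = 0.263), and camera turned down with median scaling (0.853), with cyclic loess (0.977), without C28 replicate 1 (0.921) and without JJ012 replicate 3 (0.907). GEMIN4 lost its call with median scaling (0.85) and without JJ012 replicate 2 (0.98). Of 32 ribosomal protein genes 5 were higher and none lower by limma, again 5 and none at an unadjusted p under 0.05 and 2-fold (camera adjusted p = 0.145). RPS23 rose by 1.76 (SE 0.20), with RPS7, RPL13, RPS3 and RPL37, named after their values were seen. Heat shock and immediate early genes were higher in 8 of 29 cases and lower in 3 (adjusted p = 0.561), with CRYAB at least 7.15-fold and KLF2 at 2.44 higher, and DUSP6 at −3.51, EGR1 at −1.32 and JUND, named after its value was seen, lower. DUSP6 was at −4.18 without JJ012 replicate 1. Replication-dependent histone genes, whose probes may read one another, were higher in 8 of 13 cases and lower in 3 (adjusted p = 0.063), with H2AC6 at 2.39 and H1-2 at 2.21 higher, H4C3 at −2.96 and H2BC9 at least 3.05-fold lower, and H2BC8 lower, named after its value was seen. The Replication-dependent histones list passed 0.05 without JJ012 replicate 2 (adjusted p = 0.0424).

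Markers of other cell types varied by gene. Muscle and myofibroblast markers were lower in 7 of 10 cases, with ACTG2 at −5.09, and higher in 1, ACTC1 at least 1.64-fold (adjusted p = 0.063), and ACTG2 was at −6.08 without JJ012 replicate 1 and at −4.12 without JJ012 replicate 2. Epithelial markers had 1 of 7 higher, CLDN7 at least 2.90-fold, and 2 lower (adjusted p = 0.37), KRT8 at −3.45 (2 of 3 JJ012 arrays) and EPCAM. Endothelial markers had 1 of 3 higher, PECAM1 at least 1.66-fold, and 2 lower (adjusted p = 0.612), SOX18 at −1.68 and EGFL7. Blood cell markers had 3 of 8 higher, CD68 at 2.97, CSF1R and CD3D, and 1 lower, CD14 at −2.72 (adjusted p = 0.307). Adipocyte markers had 1 of 7 higher, CIDEC at 1.06 (1 of 3 C28 arrays), and 3 lower, PPARG at −3.59 (1 of 3 JJ012 arrays), LPL and CEBPA (adjusted p = 0.37). CIDEC lost its call with median scaling (0.91). EPCAM, EGFL7, CSF1R, CD3D, LPL and CEBPA were named after their values were seen.

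Lists given without a call were not all stable in this. The lists of fibrillar matrix, WNT signalling, cell cycle genes, cell cycle inhibitors, interferon-stimulated genes, cytokines, the citrate cycle, histones and muscle markers each passed a camera adjusted p of 0.05 under at least 1 alternative. Some named genes that lay near 2-fold or near background lost their call under another treatment of background. Without background correction FZD1 read 0.76, CDC6 0.75, HLA-E 0.98, GEMIN4 0.99, CIDEC 0.48 and DHCR7 0.98, and H19, HOXD4, PECAM1, ACTC1, CCL20, ITGB3 and MAGED4, each undetected in 1 line, also fell short of 2-fold. With the authors' normalized values FZD1, CDC6, HLA-E, GEMIN4, H19, HOXD4, PECAM1, ACTC1, CIDEC and MAGED4 lost it as well. Of 39 named genes with another probe past the filter, 22 had one more than 1.5-fold apart, which in all 22 read a smaller change of the same direction, among them DCN, NACAD, MAGEC2 (5.48), MAGEA1 (5.15), DKK1 (−4.13) and DUSP6 (−2.37). GREM1, MMP11, TNFRSF11B, MSX2, PPARG and IGFBP2 were likewise detected on no JJ012 array once JJ012 replicate 1 was left out. They were then at least 12.6-fold, 7.94-fold, 7.99-fold, 5.75-fold, 11.9-fold and 3.11-fold lower. Where a gene was given as a bound, that bound is of its brightest probe. Another probe gave only at least 14.8-fold for CT55, 6.89-fold for CA12, 4.96-fold for SPP1, 2.81-fold for FGF5, 2.44-fold for PRRX1, 2.17-fold for PDGFB, 1.53-fold for TGFA and 1.42-fold for JAG2, and 2 other probes at least 2.58-fold and 3.31-fold for CTH.

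**Figure D4:**
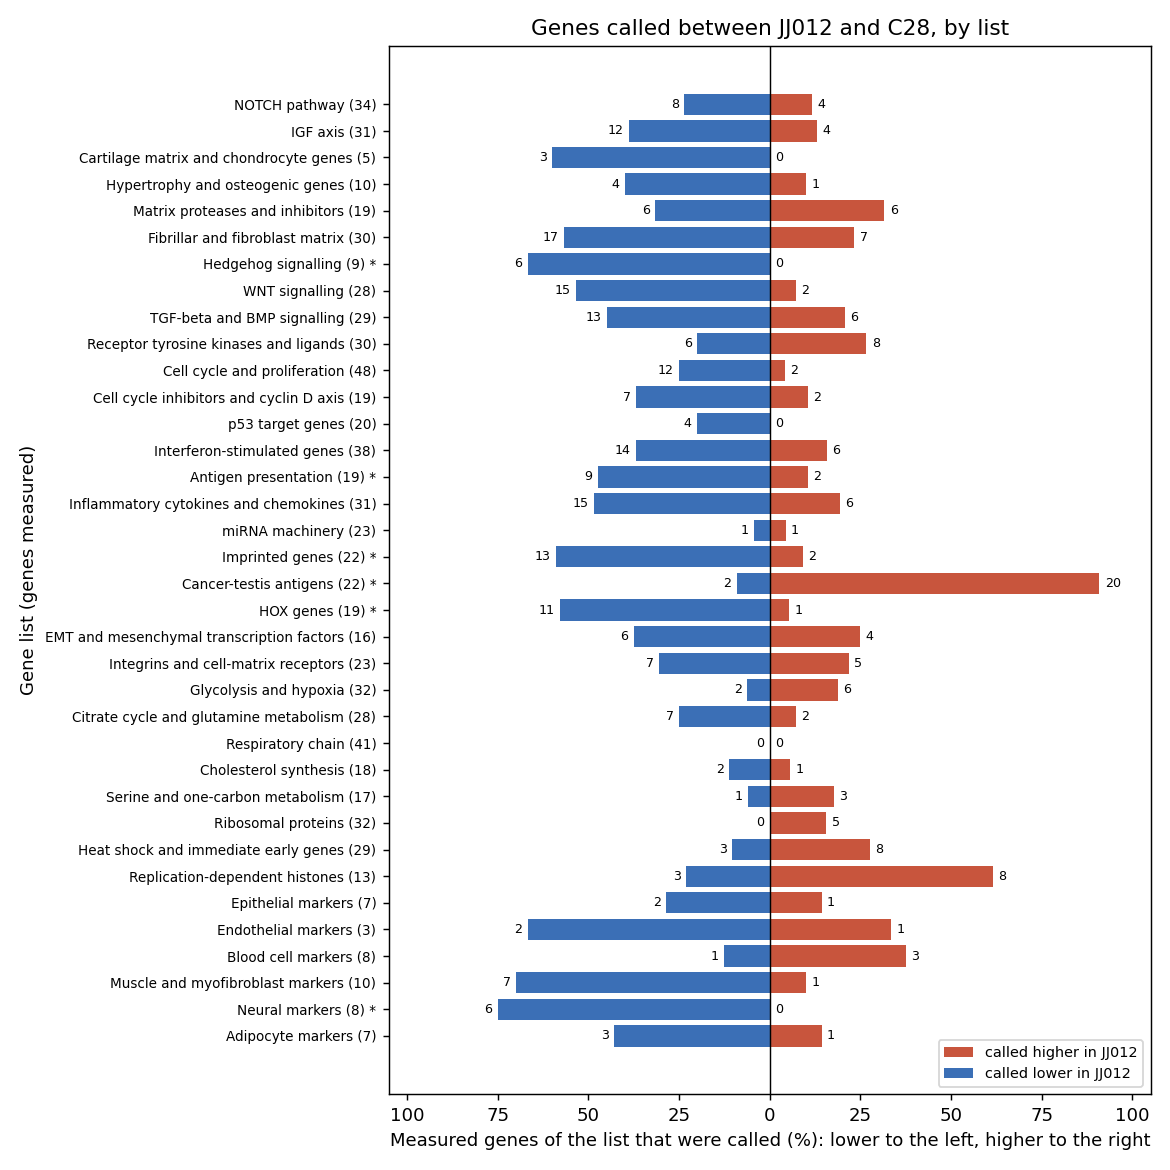
Percent of the measured genes of each list called higher (red, right) or lower (blue, left) in JJ012 by limma, with the number of genes at each bar and the number measured in brackets. Stars mark the 6 lists with a camera adjusted p under 0.05. None kept it with an estimated correlation, a setting of little power that raised p even for HOX genes, whose correlation was below the preset.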

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

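The signal reported here was found by a rule fixed before the data were examined, and no explanation of it was tested. Probes with no gene listed lay outside the comparison of genes, and some of them carried a signal above the level in the C28 control arrays. Of 3954 such probes past the detection filter, 621 were called higher and 421 lower in JJ012 by limma, and 281 were detected on all JJ012 arrays and no C28 array. Their genes were not analysed here.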

How the results depend on the processing

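Subtraction of the C28 share from JJ012 replicates 1 and 3 and the fit with JJ012 replicate 2 alone were chosen only after the data were seen, and the latter takes its spread from C28 arrays. The directions of called named genes held where an alternative gave them a value, which was so for 69 of 141 named genes with detection on all 6 arrays. The variance models, the tests at other fold limits and the setting with every probe as its own feature were run for counts only. Genes called higher and lower numbered 972 and 1284 without background correction, 1014 and 1043 with detection on all 6 arrays, 2691 and 3080 with every probe as its own feature, and 3961 and 4387 with no fold minimum. The last 3 settings change by construction what is counted, and for the others the cause was not tested. Leaving out each array in turn gave 1540 to 1612 higher and 1997 to 2079 lower genes, and subtraction of the share gave 1674 and 2153, although a C28 source stays open on replicate 3.

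For the NOTCH pathway, 2 members were higher without background correction and 2 lower with detection on all 6 arrays, and 3 to 4 were higher and 8 to 9 lower with arrays left out. For the IGF axis, 6 were lower without background correction, 7 with the authors' values and 5 with detection on all 6 arrays, and 4 were higher and 11 to 12 lower with arrays left out. The NOTCH pathway list had adjusted p-values of 0.614 (up) with detection on all 6 arrays, 0.0159 with fry and 0.606 to 0.860 with arrays left out, and the IGF axis list 0.00181 with fry and 0.138 to 0.215.

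The miRNA machinery list turned down at 0.853 with median scaling, 0.977 with cyclic loess, 0.801 with detection on all 6 arrays, 0.908 with JJ012 replicate 2 alone and 0.263 with fry, and also without C28 replicate 1 (0.921) and without JJ012 replicate 3 (0.907), in a range of 0.907 to 0.978 with arrays left out. The Serine and one-carbon metabolism list turned down at 0.958 with no filter and 0.614 with detection on all 6 arrays, and the Endothelial markers list up at 0.518 with no filter and 0.538 with a looser one. The EMT and mesenchymal transcription factors list turned up at 0.0218 with fry. IRS1, not called, ranged from −0.0884 to 0.0937 with arrays left out. Of 141 named genes, 19 lost the call without background correction, 12 with normexp without negative controls and 14 with the authors' values.

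Some lists gained a call. The Fibrillar and fibroblast matrix list reached 0.0468 without background correction, 0.0356 with no filter, 0.0220 with detection on all 6 arrays, 0.0328 with the share subtracted and 0.0146 with JJ012 replicate 2 alone, and the WNT signalling list 0.0468, 0.0429 and 0.0146 without background correction, with the share subtracted and with that array alone. The Cell cycle and proliferation list reached 0.0468, 0.0103, 0.0496 and 0.0249 without background correction, with no filter, with a looser one and with detection on all 6 arrays, and the Citrate cycle and glutamine metabolism list 0.0468, 0.0132 and 0.0297 in the first, second and last of these. The Replication-dependent histones list reached 0.0468 without background correction, 0.0470 with median scaling and 0.0227 with detection on all 6 arrays, and the Muscle and myofibroblast markers list 0.0468, 0.0297, 0.0429 and 0.0389 without background correction, with that detection, with the share subtracted and with JJ012 replicate 2 alone. The Interferon-stimulated genes list reached 0.0103 with no filter and 0.0496 with a looser one, the Cell cycle inhibitors and cyclin D axis list 0.0161 with no filter, and the Inflammatory cytokines and chemokines list 0.0198 with JJ012 replicate 2 alone. Fry, which asks another question, passed 26 lists that camera did not, in camera's direction.

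The replicate block gave the same 1572 and 2022 genes and changed no call of a list or named gene. Arrays of the same number had correlations of deviations of −0.0947, −0.111 and 0.0628, so no pairing by number was seen. These values could not exclude a weaker shared batch. A fit with the slide as a block was not run, because the files give no slide. Genes near background are limited by signal, and folds of undetected genes are bounds.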

Other observations

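The test of 1 common share of C28 signal, the test of genes switched on one by one, the choice of gene windows, and the alternatives that subtract the C28 share from JJ012 replicates 1 and 3 or use JJ012 replicate 2 alone were chosen only after the results were seen. Runs of neighbouring genes changed together. Windows left out a tested gene whose symbol shared its first 3 letters with the gene before it, and genes left out may differ. All 10 genes of the window from PRDX4 to SCARNA23, namely PRDX4, ACOT9, SAT1, APOO, KLHL15, EIF2S3, ZFX, PDK3, POLA1 and SCARNA23, were lower in JJ012, with a median log2 fold change of −1.93. PDK3, a kinase that inhibits pyruvate dehydrogenase, read −3.86, and SAT1, an enzyme of polyamine breakdown, −1.78. All 10 genes of the window from DYNC2H1 to SLC35F2, among them the growth factor gene PDGFD and the inflammatory caspase gene CASP4, were higher, with CASP4 at 2.57, and PDGFD, KBTBD3 and SLN were not detected in C28. In 1000 shuffles of gene order over 10693 windows of 10 genes, runs as full had permutation p-values of 0.002 for lower and 0.001 for higher genes. These genes were chosen after their values were seen.

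Of 1301 pairs of neighbouring genes both called, 72.9% had the same direction, against a median of 50.8% (middle 95% from 47.8% to 53.8%) in 10000 shuffles, with a permutation p of 1e-04, the smallest they can give. Probes of gene families that read one another were argued against as the whole cause, since 71.6% of the 1146 pairs whose symbols do not share 3 letters had the same direction. Gene dosage or regional silencing may account for such runs as a hypothesis, and copy number was not measured here. Whether the change arose in JJ012 or in C28 stays open.

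For the signal of C28 genes on JJ012 replicate 1, a raised background predicted more detection there of probes off on the other 5 arrays. That number was 0.409 times its median on the other arrays. Detection is set against negative controls of the same array, so a rise that these controls share could not show in it. The test therefore speaks only against a rise that spared those controls. Genes switched on one by one were argued against, since the 90th percentile of the share was 1.31 times the 10th. The limit for this was 2, set after the results were seen. Of the 57 probes, 98.2% lay within 1.5-fold of the median share. C28 RNA or cells in that sample may account for the signal by the same ratio of 1.31, so both readings rest on 1 statistic. On JJ012 replicate 3 that ratio was 2.09, above the limit of 2 set for 1 common share, so a C28 source there stays open. JJ012 replicate 2, off by selection, had a 10th to 90th percentile of −0.0967% to 1.19%. Spread of that size can raise the ratio at a low share, so the ratio on replicate 3 decides little. The dilution of JJ012 RNA that such a share would bring was not decided, with a relative log2 difference of −0.145 (bootstrap 95% interval −0.357 to 0.0378, with −0.164 from the share).

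Of the 10 splits of the 6 arrays into 3 and 3, only the real 1 gave 3594 genes called by limma, and the highest of the other splits gave 0, or 2 at an unadjusted p under 0.05 and 2-fold. Each other split put both lines in each group, so the line difference entered its spread and few calls were possible. The 10 splits are also too few for a share under 0.05.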
